A study of Homo sapiens with 10 samples.

How the data were processed

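Total RNA from HEK-293 cells was measured on Affymetrix miRNA 2.0 arrays, 1 array per sample, per the labels. The 10 samples were grouped by the siRNA named in their labels: scramble, LINC00324 siRNA 1, LINC00324 siRNA 2, LOC400043 siRNA 1 and LOC400043 siRNA 2, each with 2 arrays called biological replicates. No label says whether replicates came from separate cultures, so p-values measure only the spread between these arrays. The siRNA sequences were not used here.

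The authors deposited normalized log2 signals per probe set for all 10 arrays in a table of 20706 rows, with probe sets of many species. They also deposited 2 tables of human mature miRNAs, 1 per target, of 1130 rows each, with log2 signals, a log2 fold change of silenced over scramble and a p-value, per the file headers. limma is named in the submitters' processing notes, with no version. Background correction, summarization, the normalization method and the genome build are not given in the sources used here. The scale was taken from the values, which run from about 0 to a maximum of 16.0 on every array. The p-values of the LINC00324 table differ by at most 5e-06 from limma's moderated test on all rows of the value table with 4 silenced against 2 scramble arrays.

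The 2 human tables come from separate normalization runs. The scramble and LINC00324 columns of the value table equal the LINC00324 table, while the same 2 scramble arrays have other values in the LOC400043 table, and the LOC400043 columns of the value table belong to that run. The scramble means of the runs differ by a median of 0.07 on the log2 scale over detected probe sets, with an SD of 0.25. The LOC400043 arrays were therefore brought to the first run per probe set, by subtracting the scramble mean in the LOC400043 table minus that in the value table, so that each change against scramble is one within a run. This step was chosen after the data were seen, and the design written before assumed a single run. The authors' LOC400043 fold changes equal these changes within 5e-04. In the LOC400043 table, 4 columns of per-sample values have names that match no label and were not used. snoRNA, scaRNA and hairpin probe sets have no scramble value in the second run, so they were tested for LINC00324 silencing and between the LOC400043 siRNAs only.

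Of 1100 human mature probe sets in the value table, 1080 have a name in the authors' tables, from which names, sequences and positions were taken, and 20 were left out. There, 22 probe sets carry more than 1 miRNA name. A probe set was called detected where its mean over the 10 arrays lay above 1.31, the 95th percentile of the same mean over 2392 plant probe sets of the array. That gave 322 probe sets (29.8%), and the 99th percentile (4.50) gave 143. Where arrays of the lower group lay under the floor, the difference was also computed from the floor and is given as "at least". GC content was taken from the miRNA sequence, and 70% was set as the bound of the high class after the data were seen.

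Tests used limma 3.58.1 in R 4.3.3: lmFit with 1 mean per group over all 10 arrays, contrasts of group means, eBayes, and Benjamini-Hochberg adjustment over the tested probe sets at 0.05. Residual degrees of freedom were 5, with 1.92 prior degrees of freedom. The median SD was 0.30. Each silencing effect is the mean of the 2 siRNA groups minus scramble. Exact permutation tests of 2 arrays against 2 cannot go below p = 0.333 and were not used. The 22 lists were tested with camera (preset correlation 0.01, and estimated) and fry where at least 3 members were detected. Expected correlations and overlaps under shared controls came from 1000 simulations of unchanged groups each. The overlaps came from lists of the observed sizes taken in order of limma's moderated statistic, and also from calls past the threshold. The simulation of overlaps was chosen after the data were seen. In simulated data with 322 probe sets and 20 changed per size, the LINC00324 silencing fit recovered 27.8% of 1.5-fold changes, 54.5% of 2-fold and 85.5% of 4-fold changes, and 4.70% of its calls were wrong. The LOC400043 silencing fit recovered 29.5%, 61.5% and 87.5%. Simulated errors were normal and independent between probe sets and arrays, with SDs shuffled among probe sets. They held no shift by GC content, no deviation common to an array and no bridge between runs. The shares recovered and wrong therefore describe those conditions and need not hold for the calls here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

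The miRNAs named follow a rule fixed before the data were examined. For each silencing effect these are the 12 largest changes in each direction that passed and moved the same way with both siRNAs, filled up to 6 by the lowest p where fewer passed. For the other comparisons they are the 5 largest in each direction, for snoRNA and hairpin classes the 3 lowest p-values, and for the authors' tables the 5 lowest. For lists the rule takes up to 4 members of highest level. The text gives 2 members, and only for lists with a member or a set test past the threshold. That limit was set after the data were seen, alike for all lists.

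Alternatives fixed beforehand were no filter, the stricter floor, all probe sets, quantile normalization, centring on the median or the spike-in controls, a variance trend with robust moderation, only the arrays compared, the replicate number as a block, other thresholds, a target's arrays as 1 group, each siRNA alone, the authors' table, and leaving out each array. Added after the data were seen were a loess fit on GC content removed per array (span 0.75), only probe sets under 70% GC, the value table as deposited, the second run's scramble values, a crossed block, and correlations without each silenced array.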

Results

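MicroRNA levels were measured in HEK-293 cells, a human embryonic kidney line, after transfection of small interfering RNAs (siRNAs) at a final concentration of 10 nM. The siRNAs were directed at 1 of 2 long noncoding RNAs, LINC00324 or LOC400043, with 2 siRNAs per target, and a scramble siRNA served as the control. The series concerns long noncoding and circular RNAs that could bind microRNAs (miRNAs) as sponges, and the comparisons ask which miRNAs change in level when either RNA is silenced. There were 5 groups of 2 arrays, 10 arrays in all, and the labels call the arrays of a group biological replicates. Of 1080 human mature miRNA probe sets, 322 (29.8%) lay above the detection floor and were tested. Replicate arrays correlated across these probe sets with r between 0.973 and 0.988, and the small number of arrays limits the precision. The arrays do not measure LINC00324 or LOC400043, so the extent of silencing is unknown. Levels are log2 signals, changes are log2 differences with their standard error (SE), and adjusted p-values are from limma with Benjamini-Hochberg adjustment.

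After LINC00324 silencing, miRNAs that passed the test were almost all lower than in scramble cells. Both arms of miR-34a, a p53-induced repressor of the cell cycle, fell: miR-34a-3p by 1.79 (SE 0.23, adjusted p = 0.0102) and miR-34a-5p by 1.11 (SE 0.18, adjusted p = 0.0102), on 4 of 4 silenced arrays each. The level of miR-34a-5p was 7.85 ± 0.06 (SD, n = 2) in scramble cells, 6.41 ± 0.35 (SD, n = 2) with siRNA 1 and 7.08 ± 0.02 (SD, n = 2) with siRNA 2. The largest fall was that of miR-1909-3p (81.8% GC), by 2.19 (SE 0.32, adjusted p = 0.0102), which is 4.57-fold. Background control probe sets of at least 80% GC had a median change of −0.74 on the same arrays. miR-498, a member of the primate-specific cluster on chromosome 19, fell by 1.48 (SE 0.22, adjusted p = 0.0102). The only miRNA that rose was miR-4298, by 0.83 (SE 0.12, adjusted p = 0.0102), from 8.34 ± 0.00 (SD, n = 2) to 9.03 ± 0.08 (SD, n = 2) with siRNA 1 and 9.32 ± 0.13 (SD, n = 2) with siRNA 2.

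In this comparison 30 of 322 probe sets passed, 1 higher and 29 lower, with 74 at an unadjusted p under 0.05. Further falls were those of miR-99b-3p (−1.77), miR-3180-3p (−1.68), miR-1231 (−1.64), miR-550a-5p (−1.35), miR-218-5p (−1.27, of which siRNA 1 had −0.36), miR-3185 (−1.24), miR-3178 (−1.20), miR-1908-5p (−1.18) and miR-1181 (−1.18), with adjusted p from 0.0102 to 0.0308. For miR-99b-3p and for miR-1181, 2 of the 4 silenced arrays lay below the detection floor, so the falls were at least 1.72 and 1.08. On the higher side, miR-181c-5p (0.84, adjusted p = 0.0702), miR-3065-5p (0.78, adjusted p = 0.0906), miR-92a-1-5p (0.66, adjusted p = 0.0906), miR-1275 (0.63, adjusted p = 0.0820) and miR-25-5p (0.56, adjusted p = 0.0891) did not pass. Both scramble arrays lay below the floor for miR-181c-5p, and its difference was at least 0.41. Of the 29 that fell, 17 had a GC content of at least 70%, and the 52 detected miRNAs of that GC content had a median change of −0.70, against −0.09 for the other 270. Background control probe sets of the same GC content had a median change of −0.66 in these arrays. Among the falls named, miR-1909-3p, miR-3180-3p, miR-1231, miR-3178, miR-1908-5p and miR-1181 belong to this GC class. Without scramble replicate 1, 0 probe sets passed in limma (50 at an unadjusted p under 0.05), and without scramble replicate 2, 4 passed. The median detected signal was lower on both siRNA 2 arrays (3.45 and 3.77) than on the scramble (4.40 and 4.18) and siRNA 1 arrays (4.17 and 4.11). With each array centred on that median 0 passed (91 at an unadjusted p under 0.05), and with each array's GC trend removed 14 passed, 6 higher and 8 lower.

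**Figure D1:**
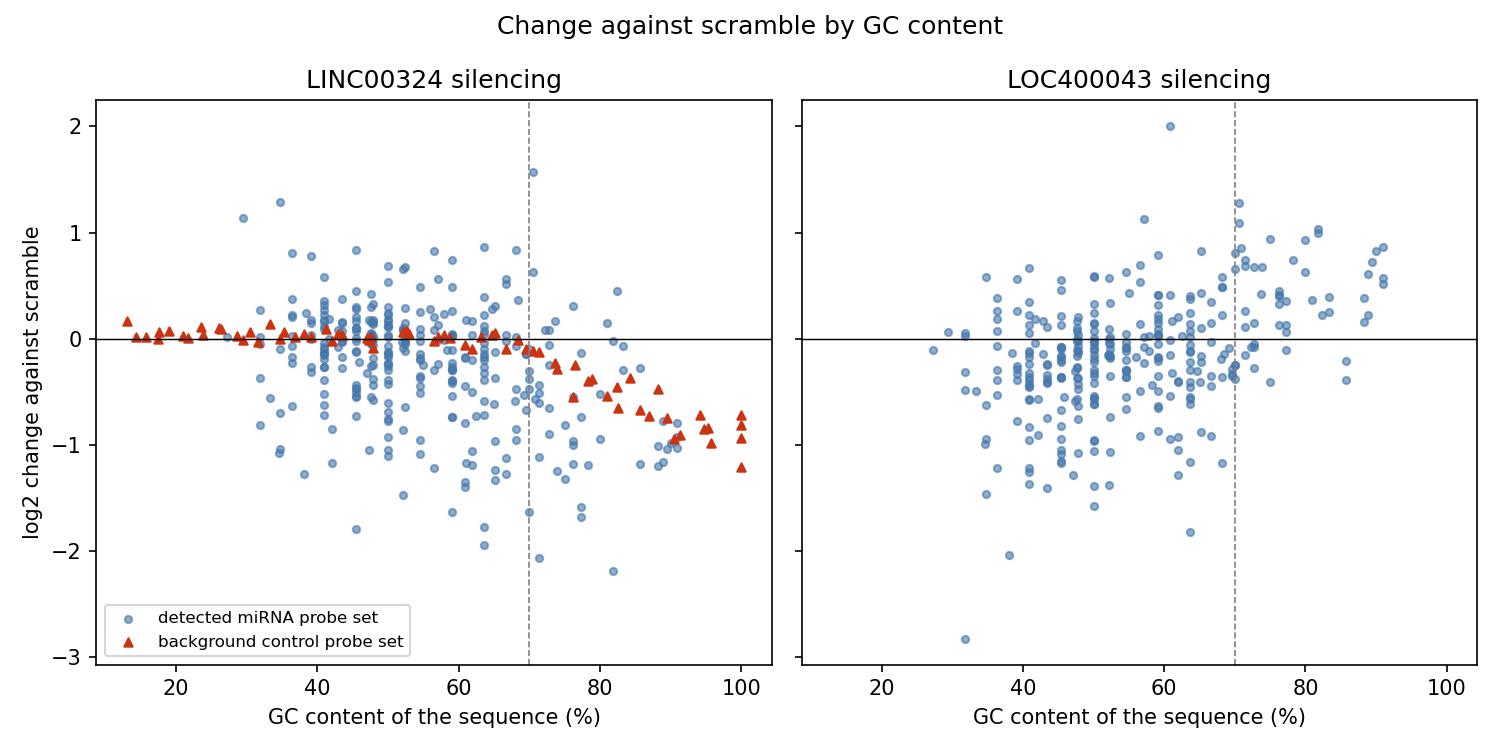
Change against scramble (vertical axis, log2) of each of the 322 detected miRNA probe sets (circles) by the GC content of its sequence (horizontal axis, percent), for LINC00324 silencing on the left and LOC400043 silencing on the right. Triangles are the 72 background control probe sets, shown for LINC00324 only, and the dashed line marks 70%, beyond which the median miRNA change was −0.70 on the left and 0.39 on the right.

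The detected miRNAs were grouped by 22 lists of families, genomic clusters and cell type markers fixed before the data were examined. For LINC00324 silencing, no list passed the camera test with its preset correlation, and 2 had an unadjusted p under 0.05. These were the miR-17 cluster with its paralogs, which drive proliferation (unadjusted p = 0.0279, adjusted p = 0.230, higher than other miRNAs, with 10 of 20 members higher), and the miR-15 and miR-16 family (unadjusted p = 0.0287, adjusted p = 0.230, 6 of 8 members higher). Their adjusted p was 0.761 each with an estimated correlation. The miR-17 cluster list had a median of −0.02 and a mean of 0.04. Among p53-responsive miRNAs, 2 of 4 detected members fell, both arms of miR-34a, and miR-194-5p was at 0.10 (adjusted p = 0.826). This list moved down in the directional fry test (adjusted p = 0.0326), which asks whether the members move one way on balance, though not with arrays centred on the median (adjusted p = 0.265). In the imprinted cluster at 14q32, 1 of 4 detected members fell, miR-323a-5p by at least 0.32 (adjusted p = 0.0250), as all 4 silenced arrays lay below the floor. miR-494-3p was at −0.73 (SE 1.08, adjusted p = 0.760), and miR-337-3p, with 3 of 4 silenced and 1 of 2 scramble arrays below the floor, did not pass (adjusted p = 0.915). Its downward fry call (adjusted p = 0.00765) was lost with the GC trend removed (adjusted p = 0.474), and with median centring the direction turned (list median 0.03, adjusted p = 0.582). miR-498 was the 1 detected member of the chromosome 19 cluster. Other lists passed fry only under another scaling. The miR-15 and miR-16 family moved up with quantile normalization (adjusted p = 0.0300), median centring (adjusted p = 0.0408) and the GC trend removed (adjusted p = 0.0179), against adjusted p = 0.0750 without them. The HOX cluster list moved up with median centring (adjusted p = 0.0408) and the GC trend removed (adjusted p = 0.0348), the mesenchymal and endothelial markers with quantile normalization (adjusted p = 0.0300) and median centring (adjusted p = 0.0408), and the let-7 family moved down with the GC trend removed (adjusted p = 0.0348).

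Among neuronal markers, 1 of 5 detected members fell, miR-7-5p by 1.04 (SE 0.22, adjusted p = 0.0250, at least 1.03 from the floor), on the 2 arrays of siRNA 2 only, and miR-128-3p was at 0.05 (adjusted p = 0.915). In the miR-181 family, 1 of 6 fell, miR-181a-2-3p by 0.96 (SE 0.23, adjusted p = 0.0441, at least 0.90 from the floor), while the abundant miR-181a-5p (0.17, adjusted p = 0.629) and miR-181b-5p (0.14, adjusted p = 0.696) did not pass. Adjusted over the list alone, 1 member of that family rose and 2 fell. In the miR-23, miR-24 and miR-27 clusters 1 of 8 fell, miR-23a-5p by at least 0.47 (adjusted p = 0.0432, all 4 silenced arrays below the floor), which was named after its value was seen, and miR-23b-3p (0.03, adjusted p = 0.930) and miR-24-3p (−0.14, adjusted p = 0.592) did not pass. The value of miR-24-3p turned to 0.28 with median centring. No member passed among the 20 of the miR-17 cluster list, the 8 each of the let-7, miR-15 and miR-16, miR-30 and HOX cluster lists, the 7 of the miR-103, miR-107, miR-26 and miR-148 families, the 5 mesenchymal and endothelial markers, the 4 each of the miR-130, miR-183 and innate immune lists, the 2 of the miR-29 family, the 2 epithelial markers and the 1 pluripotency miRNA. Of 5 detected blood cell markers none passed over all miRNAs, and 3 fell when adjusted over the list alone. None of the 8 muscle or 2 liver marker probe sets was detected. Adjusted over the list alone, the p53-responsive list again had 2 members that fell, and the chromosome 19, 14q32, neuronal and miR-23, miR-24 and miR-27 lists 1 each.

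With either LINC00324 siRNA alone, most miRNAs that passed were lower than in scramble cells, though not for siRNA 2 under other scalings. With siRNA 1, 27 of 322 probe sets passed (2 higher, 25 lower, 56 at an unadjusted p under 0.05). The largest falls were those of miR-34a-3p (−2.34, SE 0.27, adjusted p = 0.00848), miR-1909-3p (−2.08), miR-498 (−1.79), miR-3180-3p (−1.76) and miR-1231 (−1.76), and miR-181c-5p (1.09, adjusted p = 0.0485, at least 0.66 from the floor) and miR-4298 (0.69) rose. With siRNA 2, 32 passed (3 higher, 29 lower, 84 at an unadjusted p under 0.05). Here miR-7-5p, abundant in neurons and endocrine cells, fell by 2.40 (SE 0.25, adjusted p = 0.00938, at least 2.37 from the floor), followed by miR-1909-3p (−2.31), miR-218-5p (−2.18), miR-550a-5p (−1.96) and miR-99b-3p (−1.91, at least 1.82 from the floor). miR-3065-5p (1.54), miR-1972 (1.47) and miR-4298 (0.98) rose. For siRNA 2, whose arrays had the lowest median signal, quantile normalization gave 3 calls, 2 higher and 1 lower, median centring 28, 24 higher and 4 lower, and removal of the GC trend 15, 8 higher and 7 lower. For siRNA 1 these gave 26 (7 higher), 7 (0 higher) and 5 (1 higher). Fits limited to the arrays compared gave 0 calls for either siRNA (63 and 78 at an unadjusted p under 0.05 in limma), as did leaving out scramble replicate 1 (45 and 59).

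The pair of LINC00324 siRNAs was then compared directly, to ask whether 2 sequences against 1 target differ. miR-7-5p was lower with siRNA 2 than with siRNA 1 by 2.72 on the log2 scale (−2.72, SE 0.25, adjusted p = 0.00419), with 1 of 2 siRNA 2 arrays below the floor (at least 2.69). Also lower with siRNA 2 were miR-218-5p (−1.81), miR-708-5p (−1.63), miR-149-5p (−1.28), miR-196a-5p (−1.09) and miR-222-5p (−1.02), the last named after its value was seen, and miR-3065-5p was higher (1.52). These 7 of 322 passed with adjusted p from 0.00419 to 0.0375, and 48 had an unadjusted p under 0.05. Leaving out 1 of the 4 arrays in turn left between 1 and 3, a fit limited to these arrays 0 in limma (40 at an unadjusted p under 0.05) and the replicate block 1. Quantile normalization, removal of the GC trend and a fit of all probe sets left 2 each, all lower, and median centring 3, 2 higher and 1 lower.

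After LOC400043 silencing, the largest change past the test was that of let-7f-5p, a member of the let-7 family of differentiation-associated miRNAs. It fell by 2.83 (SE 0.31, adjusted p = 0.0146), or 7.11-fold, on 4 of 4 silenced arrays. In the same normalization run its level was 4.91 ± 0.15 (SD, n = 2) in scramble cells and had means of 2.19 with siRNA 1 and 1.96 with siRNA 2. miR-218-5p fell by 2.04 (SE 0.28, adjusted p = 0.0217) and miR-7-5p by 1.46 (SE 0.22, adjusted p = 0.0217). miR-25-5p, the passenger arm of a miRNA of the miR-106b-25 cluster, rose by 1.13 (SE 0.16, adjusted p = 0.0217), and miR-1275 rose by 1.09 (SE 0.18, adjusted p = 0.0294).

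These 5 of 322 probe sets passed, 2 higher and 3 lower, with 81 at an unadjusted p under 0.05. miR-3188 (2.00), miR-1469 (0.86), miR-1915-3p (0.83) and miR-2861 (0.72) on the higher side and miR-34a-3p (−1.08), miR-96-5p (−0.78) and miR-18b-5p (−0.75) on the lower side did not pass, with adjusted p = 0.0574 each. All 4 silenced arrays lay below the floor for miR-96-5p, and its difference was at least 0.64. The 52 miRNAs of at least 70% GC had a median change of 0.39 and the other 270 one of −0.19, and miR-1275 (70.6% GC) belongs to the former. The background controls of that GC content lay between −0.02 and 0.41 above scramble on the 4 LOC400043 arrays, a level set across 2 normalization runs. Without scramble replicate 1, without scramble replicate 2 or without LOC400043 siRNA 1 replicate 2, 0 passed in limma (47, 53 and 69 at an unadjusted p under 0.05). With the stricter detection floor 39 passed, with a variance trend and robust moderation 40, with the value table as deposited 21 (13 higher, 8 lower), with the second run's scramble values and spread 11 (4 higher, 7 lower), with median centring 12 (10 higher, 2 lower), with quantile normalization 5 (4 higher, 1 lower), with the GC trend removed 2, let-7f-5p and miR-25-5p, and with the target's arrays as 1 group or each siRNA alone 1.

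No list passed camera for LOC400043 silencing, and 2 had an unadjusted p under 0.05. These were the let-7 family (unadjusted p = 0.00463, adjusted p = 0.0741, 7 of 8 members lower) and the miR-30 family (unadjusted p = 0.0157, adjusted p = 0.125, 8 of 8 lower). With an estimated correlation the adjusted p was 0.643 and 0.706. In the let-7 list 1 of 8 fell, let-7f-5p, and 4 fell when adjusted over the list alone, while let-7a-5p (−0.53, adjusted p = 0.108) and let-7e-5p (0.06, adjusted p = 0.825) did not pass. The list moved down in the fry test (adjusted p = 0.0108), and its median of −0.74 became −0.57 after quantile normalization, −0.47 with median centring, where the fry call was lost (adjusted p = 0.0825), and −0.43 with the GC trend removed. In the miR-17 cluster list 1 of 20 rose, miR-25-5p, while the abundant miR-17-5p (−0.47, adjusted p = 0.0586) and miR-20a-5p (−0.29, adjusted p = 0.163) did not pass, and adjusted over the list alone 1 rose and 5 fell. Its downward fry call (adjusted p = 0.0178, list median −0.19) was lost with quantile normalization (adjusted p = 0.0706) and turned upward without passing under median centring (list median 0.07, adjusted p = 0.726) and with the GC trend removed (list median 0.07, adjusted p = 0.528). In the miR-15 and miR-16 list 0 of 8 passed (2 fell over the list alone), with miR-16-5p at −0.08 (adjusted p = 0.734) and miR-15b-5p at −0.43 (adjusted p = 0.0947). Its downward fry call (adjusted p = 0.0153) was lost with quantile normalization (adjusted p = 0.0587), with the GC trend removed (adjusted p = 0.362) and with median centring (adjusted p = 0.735), where miR-16-5p was at 0.19.

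Of 5 mesenchymal and endothelial markers, which could mark other cell types, 0 passed (2 fell over the list alone). miR-221-3p was at −0.14 (adjusted p = 0.590) and miR-222-3p at −0.18 (adjusted p = 0.406), and the sign of both turned with median centring (0.13 and 0.087). Their list's downward fry call (adjusted p = 0.0336) was lost there (adjusted p = 0.721, list median 0.09) and with the GC trend removed (adjusted p = 0.884). Among 5 neuronal markers 1 fell, miR-7-5p, with miR-128-3p at −0.57 (adjusted p = 0.108), and 2 fell over the list alone. No member passed in the other lists. Over the list alone, 2 p53-responsive miRNAs, 1 miR-30 and 1 miR-183 cluster member fell.

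With LOC400043 siRNAs taken singly, let-7f-5p was the 1 call they shared. With siRNA 1, 19 passed (11 higher, 8 lower, 76 at an unadjusted p under 0.05), and 9 of the 11 that rose had at least 70% GC. miR-218-5p fell by 3.09 (SE 0.32, adjusted p = 0.00974), let-7f-5p by 2.71, miR-7-5p by 2.08, miR-181a-2-3p by 1.38 (both siRNA 1 arrays below the floor, at least 1.28) and miR-19a-3p by 1.15. miR-3188 (2.37), miR-1469 (1.22), miR-3185 (1.19), miR-939-5p (1.12) and miR-1915-3p (1.11) rose. With siRNA 2, 5 passed (2 higher, 3 lower, 54 at an unadjusted p under 0.05): let-7f-5p (−2.94), miR-34a-3p (−2.07) and miR-34a-5p (−1.23) fell, and miR-25-5p (1.62) and miR-1275 (2.83-fold) rose. The replicate arrays of siRNA 2 differed in let-7f-5p (SD 0.88, n = 2). Without scramble replicate 1, 0 passed for either siRNA (50 and 32 at an unadjusted p under 0.05 in limma). With the GC trend removed siRNA 1 had 2 calls, both lower, so that none of its rises passed.

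Compared directly, the LOC400043 siRNAs differed in both arms of miR-34a and in miR-218-5p. miR-34a-3p (−1.97, SE 0.27, adjusted p = 0.0255) and miR-34a-5p (−1.38, SE 0.20, adjusted p = 0.0279) were lower with siRNA 2, as was miR-3178 (−0.98, adjusted p = 0.0399, 88.2% GC). miR-181a-2-3p (at least 2.06, adjusted p = 0.0255, both siRNA 1 arrays below the floor) and miR-218-5p (2.09, SE 0.32, adjusted p = 0.0279) were higher with siRNA 2. These 5 of 322 passed, with 45 at an unadjusted p under 0.05, and leaving out 1 array in turn left 0 or 1. A fit limited to these arrays and the replicate block left 2 each, and median centring and removal of the GC trend 3 each, while the stricter floor gave 9 and a variance trend with robust moderation 18. Background controls of at least 80% GC differed between these siRNAs by −0.58 (n = 18 probe sets).

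**Figure D2:**
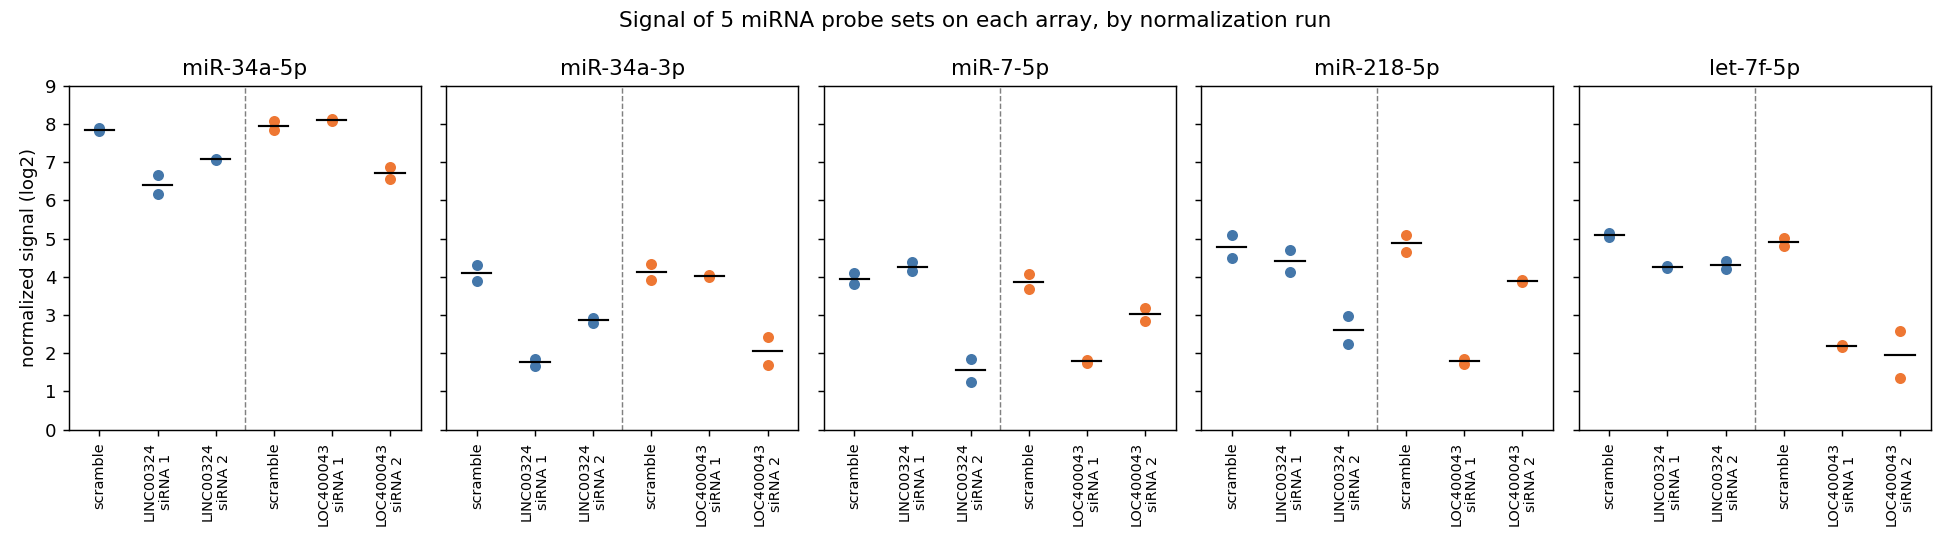
Normalized log2 signal (vertical axis) of 5 miRNA probe sets on each array by group (horizontal axis), with points for arrays and bars for the mean of 2 arrays. The LINC00324 run lies left of the dashed line and the LOC400043 run right of it, and the same 2 scramble arrays appear in both with the values of each run. miR-34a-5p lay lowest with LINC00324 siRNA 1 and LOC400043 siRNA 2, and miR-7-5p with LINC00324 siRNA 2 and LOC400043 siRNA 1.

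For the miRNAs with 1 genomic position in the authors' tables, the positions of the precursors were as follows, in a genome build not given in the sources used here. Both miR-34a arms (miR-34a-5p, UGGCAGUGUCUUAGCUGGUUGU) lie on chromosome 1 from 9211727 to 9211836, miR-498 (UUUCAAGCCAGGGGGCGUUUUUC) on chromosome 19 from 54177451 to 54177574 and miR-25-5p (AGGCGGAGACUUGGGCAAUUG) on chromosome 7 from 99691183 to 99691266. miR-1909-3p (CGCAGGGGCCGGGUGCUCACCG) lies on chromosome 19 from 1816158 to 1816237, miR-4298 (CUGGGACAGGAGGAGGAGGCAG) on chromosome 11 from 1880694 to 1880766 and miR-1275 (GUGGGGGAGAGGCUGUC) on chromosome 6 from 33967749 to 33967828. No single position was used for let-7f-5p (UGAGGUAGUAGAUUGUAUAGUU), miR-7-5p (UGGAAGACUAGUGAUUUUGUUGU) and miR-218-5p (UUGUGCUUGAUCUAACCAUGU).

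The effects of silencing the 2 RNAs were compared with each other through the 8 silenced arrays. After LINC00324 silencing GC-rich miRNAs were lower, and let-7f-5p and the miR-17 cluster relatives miR-19a-3p and miR-20b-5p higher, than after LOC400043 silencing. miR-1909-3p differed by −3.19 (SE 0.26, adjusted p = 0.000289), or 9.12-fold, followed by miR-3188 (−2.80), miR-1910-5p (−2.75), miR-1231 (−2.44) and miR-3187-3p (−2.27). let-7f-5p differed by 2.02 (SE 0.26, adjusted p = 0.00182), followed by miR-181d-5p (1.78), miR-4306 (0.97, at least 0.80 from the floor), miR-19a-3p (0.85) and miR-20b-5p (0.79). Of 322 probe sets 77 passed, 30 higher and 47 lower, with 112 at an unadjusted p under 0.05. All 32 that passed with at least 70% GC were lower, and the median difference was −1.03 for that class and 0.12 for the rest. From 80% GC it was −1.44, while background controls of that GC content moved against scramble by −0.74 on LINC00324 arrays and by 0.34 on LOC400043 arrays, the latter across runs. Among probe sets under 70% GC alone, 35 passed, 22 higher and 13 lower. Because the runs were normalized apart, this is the difference of changes that were each measured against scramble within a run. Its SEs and adjusted p-values leave out the error of the bridge between runs. Leaving out scramble replicate 1, which changes these differences only through the bridge, moved miR-1909-3p to −3.40 and miR-4306 to 1.21. Without scramble replicate 2 they were at −2.98 and 0.72.

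Calls were also compared between siRNAs. Of 25 and 29 miRNAs that fell with LINC00324 siRNA 1 and siRNA 2, 19 were shared, 13 of them with at least 70% GC, where background controls were lower as well. Lists of these sizes from unchanged groups, simulated against the same scramble arrays, shared 9.21 on average and at most 16 in 1000 simulations. Independent lists would share 2.25. Probe sets were simulated independently, without the fall that GC-rich probe sets had in common on LINC00324 arrays. The 19 shared falls therefore do not tell a shared effect of the siRNAs from that common fall. miR-4298 rose with both, against 0.443 simulated. For LOC400043, 1 of 8 and 3 was shared (let-7f-5p, against 1.01 simulated and 0.0745 for independent lists). Between targets, miR-218-5p and miR-7-5p were the 2 shared falls among 29 and 3, against 2.25 simulated and 0.270 for independent lists. Neither this count nor that for LOC400043 stood above the one simulated with lists of the observed sizes. Past the threshold itself, unchanged groups shared fewer falls on average, 0.003 between targets, 0.001 for LOC400043 and 0.002 for LINC00324. Lists of fixed size and calls answer different questions, and neither shows how far shared scramble arrays added to these overlaps. For LINC00324 the falls of miR-218-5p and miR-7-5p rested on siRNA 2. With siRNA 1 miR-7-5p was at 0.32 (SE 0.25, adjusted p = 0.585) and miR-218-5p at −0.36 (SE 0.32, adjusted p = 0.615). Across the 322 probe sets, which are not independent replicates, the changes with 2 siRNAs of 1 target correlated with Pearson's r = 0.609 (LINC00324) and r = 0.632 (LOC400043). Unchanged groups simulated against the same 2 scramble arrays gave r = 0.499 and r = 0.501, with 95% of simulations below 0.606 and 0.600. The covariance was 0.246 and 0.247, against 0.0771 and 0.0774 simulated. Between targets r ran from −0.0876 to 0.381, and the covariance less the simulated one from −0.113 to 0.0672. Among the 270 probe sets under 70% GC, r was 0.527 (LINC00324) and 0.609 (LOC400043) while 95% of simulations lay below 0.616 for both, so that neither stood above the simulated range. Between targets it ran there from 0.169 to 0.516. The covariance less the simulated one was 0.102 and 0.136 within targets and from −0.0205 to 0.104 between them. The controls were not split, since each part would hold 1 scramble array, so part of any excess may come from the shared controls.

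The array also carries small nucleolar RNAs (snoRNAs), which guide the modification of ribosomal RNA, and miRNA hairpin precursors. Against scramble they were compared for LINC00324 silencing only, since the 2 runs could not be bridged for them. Of 314 detected snoRNA and scaRNA probe sets 0 passed in limma, and 72 had an unadjusted p under 0.05, 66 higher and 6 lower. The lowest p-values were those of HBII-202 (0.87), U14B (0.78, at least 0.71 from the floor) and U41 (0.94), with adjusted p = 0.0805 each. Of 83 detected hairpin probe sets, 1 passed: the precursor mir-3180-1 fell by 0.96 (SE 0.18, adjusted p = 0.0401), and mir-1308 (0.60) and mir-663b (−0.75, at least 0.58 from the floor) did not pass (adjusted p = 0.0711 each). Without either scramble array 0 hairpins passed. Between the LOC400043 siRNAs, 0 of 314 snoRNA and scaRNA probe sets passed in limma, with 56 at an unadjusted p under 0.05, 55 of them higher with siRNA 2 and 1 lower. Of the 83 hairpins 0 passed there, with 13 at an unadjusted p under 0.05, 5 higher and 8 lower.

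In the authors' deposited table for LINC00324, 126 probe sets had a p-value under 0.05, 26 higher and 100 lower, and 22 passed after Benjamini-Hochberg adjustment of those p-values, 1 higher and 21 lower. The lowest p-values in the authors' deposited table were those of miR-3178 (−1.20, p = 4e-05), miR-1228-5p (p = 4e-05), miR-149-3p (p = 4e-05), miR-3196 (p = 5e-05) and miR-1908-5p (−1.18, p = 7e-05). In the authors' deposited table for LOC400043, 121 had a p-value under 0.05, 41 higher and 80 lower, and 2 passed after adjustment, both lower. The lowest p-values in the authors' deposited table for LOC400043 were those of let-7f-5p (−2.83, p = 2e-05), let-7g-5p (−1.22, p = 4e-05), miR-96-5p (−0.78, p = 0.00025), miR-4306 (−1.29, p = 0.0003) and miR-3188 (2.00, p = 0.00043).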

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

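The tests in this part were chosen after the results they concern had been seen, except the count of other splits of the arrays.

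LINC00324 and LOC400043 silencing differed in 77 of 322 miRNA probe sets, a difference between targets that was tested directly. With the siRNA left out of the model, the real split of the 8 silenced arrays into 4 and 4 gave 47 probe sets. It was the 1 of 35 splits that gave as many, a share under the 0.05 set beforehand, and the highest of the others was 1. Arrays of 1 siRNA are not independent units, however, and the real split is also that of the normalization runs. This count therefore does not exclude chance or a shift between runs. With siRNAs as the units, only 3 splits keep both arrays of each siRNA together, too few for a share under 0.05, and the other 2 of these gave 0 each in limma. As the targets were normalized in separate runs, target and run are bridged only through the 2 scramble arrays.

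Background control probe sets, which no comparison used, carried a signal that moved with the groups: the 26 controls of at least 70% GC had a median change of −0.66 in LINC00324 arrays, all 26 lower, and on 4 of 4 arrays their median lay below both scramble arrays. GC-rich miRNAs moved with them, so a background that depends on GC content may be part of their fall. The controls changed less than the miRNAs, by −0.27 against −0.57 from 70 to 80% GC and by −0.74 against −0.93 from 80%. However, high-GC controls had medians of 1.93 and 1.85 on the scramble arrays and of 1.13 to 1.39 on the LINC00324 arrays. The latter lay near the detection floor of 1.31. That floor is not the lowest signal, as low-GC controls had medians of 0.76 to 0.83 on these arrays. Whether the fall of the high-GC controls was cut short was not tested. The smaller change of the controls therefore does not show a part of the miRNA fall that background leaves unexplained. The share of background stays open, as does an effect of silencing, which the design does not separate from the arrays. Under 70% GC, 12 miRNAs passed as lower (median −1.20), while the 32 controls of 30 to 70% GC stayed near scramble (median 0.016, range −0.10 to 0.14). Low-GC controls had medians of 0.77 and 0.76 on the scramble arrays, below the detection floor. With so little room to fall, the controls cannot decide whether a GC-dependent background lowered these 12 miRNAs. The mean of the spike-in controls changed by 0.026. The deposited signals were already normalized, and their maximum was the same on every array. A change in the scale of whole arrays could have been removed by that step, so the spike-in controls cannot decide on it. A lower signal of all miRNAs alike is argued against as the whole cause of the GC-rich falls. Within an array, the gap between GC-rich and other miRNAs was −0.35 or lower on each LINC00324 array and −0.083 on the lower scramble array. As a part of the falls a lower miRNA signal stays open, since the median detected signal of both siRNA 2 arrays stood apart (3.45 and 3.77, against 4.40 and 4.18 in scramble) and with arrays centred on it the 29 falls shrank from a median of −1.13 (median SE 0.19) to −0.71 (median SE 0.23), none passing, and the GC-rich median with siRNA 2 went from −0.65 to 0.032.

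The siRNAs of a target differed in 7 probe sets for LINC00324 and in 5 for LOC400043, also tested directly, with miR-34a passing only for LOC400043, miR-7-5p only for LINC00324 and miR-218-5p for both, though fits limited to the arrays compared left 0 (40 at an unadjusted p under 0.05 in limma) and 2. Among the means of the 5 groups, miR-34a was lowest with LINC00324 siRNA 1 and LOC400043 siRNA 2, and miR-7-5p and miR-218-5p with LINC00324 siRNA 2 and LOC400043 siRNA 1, across targets. In these groups the higher silenced array lay below the lower scramble array of its run by at least 0.95 for miR-34a and 1.52 for the others. The falls thus did not rest on a single array. Such a gap is likely for probe sets chosen as calls, so it adds little support. With the GC trend removed the smallest falls were −1.04 and −1.69. Removing a smooth trend was unlikely to undo large changes chosen as calls, so this test adds little support. Each of the 8 changes kept at least 0.811 of its size, so the fitted trend was the smaller part of each. Among them 2 calls ended, miR-34a-5p with LOC400043 siRNA 2 (−1.23, SE 0.20, to −1.04, SE 0.20, adjusted p = 0.0884), whose change shrank at a like SE, and miR-7-5p with LOC400043 siRNA 1 (−2.08, SE 0.25, to −1.69, SE 0.28, adjusted p = 0.0619), which would have passed had the other p-values stayed (adjusted p = 0.0353) and ended as the calls of that comparison went from 19 to 2. An effect of each siRNA's own sequence may underlie the pattern and was not tested, since sequences were not used here. Unequal silencing alone would make all falls larger with the same siRNA. For LOC400043, miR-34a-3p (−1.97, SE 0.27) and miR-34a-5p (−1.38, SE 0.20) were lower with siRNA 2. miR-218-5p (2.09, SE 0.32) was higher with it, which argues against unequal silencing as the whole cause there. As a part, and for LINC00324, it stays open, since target levels were not used.

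Among hairpin precursors, which lie outside the main measurement, 1 probe set passed after LINC00324 silencing, mir-3180-1. The mature miR-3180-3p has 77.3% GC, a content at which background controls were lower on these arrays. Whether background lowered the hairpin signal was not tested.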

How the results depend on the processing

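The alternatives of GC content, of bridging, of crossed numbers and of correlations without each silenced array were chosen after seeing the data, and all others before. Over the named miRNAs, 868 of 1098 alternative values kept direction and side of the threshold, 174 kept direction but no longer passed, 44 newly passed and 12 changed sign. When single arrays were left out, 344 of 558 kept both, 203 no longer passed, 1 newly passed and 10 changed sign. Over the full naming rule (216 values, 116 of them list members not given in the text), 173 of 3754 alternative values had the other sign, and 0 of those passed in either setting. Unless stated, the cause was not tested. Signal over background limits the low miRNAs, as 143 of 322 detected probe sets lay above the stricter floor.

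Counts below are of probe sets past the threshold, against 30 for LINC00324 silencing (1 higher, 29 lower), 5 for LOC400043 silencing (2 and 3), 27 (2 and 25) and 32 (3 and 29) for LINC00324 siRNA 1 and siRNA 2, 19 (11 and 8) and 5 (2 and 3) for LOC400043 siRNA 1 and siRNA 2, 7 (1 and 6) between the LINC00324 siRNAs, 5 (2 and 3) between the LOC400043 siRNAs, and 77 (30 and 47) between targets.

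Scaling moved the median change of all miRNAs from −0.14 for LINC00324 and −0.14 for LOC400043 to 0.28 and 0.13 with median centring, 0.0025 and −0.045 with quantile normalization and 0.023 and −0.0020 with the GC trend removed. With median centring LINC00324 silencing had 0 (91 at an unadjusted p under 0.05 in limma), LOC400043 silencing 12 (10 higher, 2 lower), LINC00324 siRNA 1 7 (0 and 7), LINC00324 siRNA 2 28 (24 higher, 4 lower), LOC400043 siRNA 1 17 (14 and 3), the LINC00324 siRNAs 3 (2 and 1) and the LOC400043 siRNAs 3 (2 and 1), and 1 list passed for LINC00324 (the miR-17 cluster, up) and 2 for LOC400043 (let-7 and miR-30, down), none of them in fry (adjusted p = 0.0684, 0.0825 and 0.532) or with an estimated correlation (adjusted p = 0.855, 0.511 and 0.949). In fry, LINC00324 silencing then moved up the miR-15 and miR-16, HOX cluster and mesenchymal and endothelial lists (adjusted p = 0.0408 each). With quantile normalization LINC00324 silencing had 23 (5 higher, 18 lower), its siRNA 1 26 (7 and 19), LOC400043 silencing 5 (4 and 1), LINC00324 siRNA 2 3 (2 and 1), LOC400043 siRNA 1 11 (4 and 7) and the LINC00324 siRNAs 2 (0 and 2). With the GC trend removed LINC00324 silencing had 14 (6 higher, 8 lower), LOC400043 silencing 2 (1 and 1), LINC00324 siRNA 1 5 (1 and 4), LINC00324 siRNA 2 15 (8 and 7), LOC400043 siRNA 1 2 (0 and 2), the LINC00324 siRNAs 2 (0 and 2) and the LOC400043 siRNAs 3 (1 and 2). Under 70% GC alone LINC00324 silencing had 9, LINC00324 siRNA 1 6, LINC00324 siRNA 2 10, LOC400043 siRNA 1 7 and the targets 35, with fewer probe sets tested. The mean correlation between siRNAs of different targets went from 0.164 to 0.318 with the GC trend removed and 0.362 under 70% GC.

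The stricter floor gave LOC400043 silencing 39, its siRNA 1 42, its siRNA 2 17 and the LOC400043 siRNAs 9. A variance trend with robust moderation gave 40, 44, 11 and 18 for the same comparisons. All probe sets gave LINC00324 siRNA 2 13 and the LINC00324 siRNAs 2, and no filter gave LINC00324 siRNA 2 20 and 3 lists for LOC400043 (the miR-17 cluster, let-7 and miR-30, down), with adjusted p = 0.360, 0.276 and 0.378 with an estimated correlation and adjusted p = 0.0184, 0.0141 and 0.132 in fry. With only the arrays compared, and so fewer arrays, LINC00324 silencing had 19, LOC400043 siRNA 1 5, the LOC400043 siRNAs 2, and 0 remained for LINC00324 siRNA 1, LINC00324 siRNA 2, LOC400043 siRNA 2 and the LINC00324 siRNAs (63, 78, 52 and 40 at an unadjusted p under 0.05 in limma). An adjusted p under 0.1 gave LOC400043 silencing 36, LINC00324 siRNA 2 53, LOC400043 siRNA 1 51 and LOC400043 siRNA 2 13. An unadjusted p under 0.05 with a 1.5-fold change gave 61 and 49 for the silencing effects, 49 and 74 for the LINC00324 siRNAs 1 and 2, 65 and 38 for those to LOC400043, and 35 and 35 between siRNAs. For LOC400043 silencing, the target's arrays as 1 group gave 1, and passing with each siRNA alone gave 1. The value table as deposited gave LOC400043 silencing 21 (13 and 8), its siRNA 1 29 (19 and 10) and its siRNA 2 9 (5 and 4), and the second run's scramble values and spread gave LOC400043 silencing 11 (4 and 7).

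Same-numbered arrays correlated in their deviations with r from −0.142 to 0.156, so the numbers do not pair the arrays. With the replicate number as a block, LOC400043 siRNA 1 had 9, the LINC00324 siRNAs 1, the LOC400043 siRNAs 2 and the hairpins 2, and no other count moved by over 1.5 times. With crossed numbers LINC00324 siRNA 1 had 17.

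Leaving out each array, with a lone array assumed to vary like the other groups, the counts ran from 0 to 32 for LINC00324 silencing, 0 to 5 for LOC400043 silencing, 0 to 25 and 0 to 24 for LINC00324 siRNA 1 and 2, 0 to 1 and 0 to 4 for LOC400043 siRNA 1 and 2, 1 to 3 between the LINC00324 siRNAs, 0 to 1 between the LOC400043 siRNAs and 51 to 73 between targets. For lists they ran from 0 to 0 (LINC00324) and 0 to 2 (LOC400043), for hairpins and for snoRNAs from 0 to 1. Mean correlations, 0.621 within and 0.164 between targets with all arrays, ran from 0.539 (without LOC400043 siRNA 2 replicate 1) to 0.686 (without scramble replicate 2) within and from 0.110 (without LOC400043 siRNA 2 replicate 2) to 0.276 (without scramble replicate 2) between. Without scramble replicate 1 each of the 6 comparisons with scramble had 0 (32 to 59 at an unadjusted p under 0.05), and without scramble replicate 2 they had 4, 0, 2, 4, 1 and 0 in the order above. LOC400043 silencing had 0 without siRNA 1 replicate 2 (69), 1 without siRNA 2 replicate 1 and 2 without siRNA 2 replicate 2. LINC00324 siRNA 1 had 0 without its replicate 1 (51) and siRNA 2 had 6 without its replicate 1. LOC400043 siRNA 1 had 0 without its replicate 1 (53) or its replicate 2 (58), and siRNA 2 had 2 without its replicate 1. Between siRNAs, each array left out lowered the count, and for LOC400043 it was 0 without siRNA 1 replicate 1, siRNA 1 replicate 2 or siRNA 2 replicate 2 (32 each). For LOC400043, 1 list passed without scramble replicate 2 (let-7, adjusted p = 0.576 with an estimated correlation and adjusted p = 0.0211 in fry) and 2 without siRNA 2 replicate 2 (let-7 and miR-30, adjusted p = 0.345 each with an estimated correlation, and adjusted p = 0.00101 and 0.000695 in fry). The targets had 51 without replicate 1 of either LINC00324 siRNA.

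Values of the following miRNAs, none of which passed, changed sign. For LINC00324 silencing, miR-24-3p was at 0.28 with median centring and 0.0029 with the GC trend removed, and miR-337-3p, close to the detection floor, at 0.29 with median centring. For LOC400043 silencing, miR-20a-5p was at 0.040 with quantile normalization and 0.019 with the GC trend removed, miR-16-5p at 0.19 with median centring, 0.19 with the GC trend removed and 0.026 as deposited, miR-221-3p at 0.13 and 0.11 and miR-222-3p at 0.087 and 0.021 with median centring and the GC trend removed. With single arrays left out, LINC00324 silencing ranged from −0.017 to 0.21 for miR-194-5p, −0.11 to 0.21 for miR-128-3p, −0.056 to 0.11 for miR-23b-3p, −0.43 to 0.17 for miR-337-3p and −1.68 to 0.22 for miR-494-3p, and LOC400043 silencing from −0.030 to 0.14 for let-7e-5p. Not run were all probe sets and spike-in centring for comparisons across the 2 runs, and the authors' LOC400043 table, in which 4 columns of per-sample values match no label.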

Other observations

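In this part the comparison with let-7a-5p and the test of the GC trend were chosen after the results had been seen. Members of the let-7 family differ from let-7f-5p by few bases, and their changes after LOC400043 silencing were uneven. let-7g-5p (2 differences) was at −1.22 (SE 0.28, adjusted p = 0.0586), let-7i-5p (4 differences) at −0.95, let-7b-5p (3 differences) at −0.95 (SE 0.54), let-7d-5p (3 differences) at −0.39 and let-7c-5p (2 differences) at −0.11. After LINC00324 silencing let-7f-5p was at −0.81 (adjusted p = 0.181) and let-7g-5p at −0.64 (adjusted p = 0.233).

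Signal of let-7a-5p, which differs by 1 base, is argued against as the whole source of the let-7f-5p fall. let-7a-5p was at −0.53, and the difference of −2.30 between them had an SE of 0.35. That SE treats the 2 probe sets as independent, though both were read on the same arrays. Other members of the family were not tested as a source, so signal shared with them stays open. With the GC trend removed the fall was −2.48 (SE 0.25, adjusted p = 0.00742), so the fitted trend was the smaller part of it. Such an outcome was likely for a fall chosen for its size, so it adds little support. The let-7f-5p call was lost without scramble replicate 1 (−2.72), without scramble replicate 2 (−2.94) and without LOC400043 siRNA 1 replicate 2 (−2.85). In the alternatives that left out no array of the groups compared and tested it, its adjusted p in limma ran from 0.0012 to 0.046. At the stricter detection floor of 4.50 it was not tested, since its mean lay below that floor. A biological effect of LOC400043 silencing stays open as a hypothesis, as does an off-target effect of the siRNAs, which was not tested.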
